A study of Arabidopsis thaliana with 4 samples.

How the data were processed

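Total RNA from roots of 4 groups of Arabidopsis thaliana seedlings was extracted with Trizol, copied with random primers and sequenced on an Illumina HiSeq instrument or, when necessary, another sequencer, per the labels' protocols. The protocols name root tips and also, in 1 place, shoots and roots. Groups were taken from the sample titles: Col and ein3eil1, each without and with 150 µM CdSO4 for 6 h, at 5 days of age, with 1 library per group. The aligner, the counting tool, the strand setting and the genome build are not given in the sources used here.

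The authors deposited 2 tables, 1 per genotype, that set the Cd library against the control library. Per the file headers, each row gives for a gene model the read count of both libraries, their RPKM values (reads per kilobase of model length, scaled by the total reads of the library), the log2 ratio of the RPKM values, a p-value and an FDR. Tested on the files, the authors' read counts are whole numbers, and the deposited RPKM is the count divided by model length and 1 constant per library, which gives the library total. Where the deposited read count is 0, the authors' RPKM is 0.001. The deposited log2 ratio equals the ratio of the deposited RPKM values. Every listed model has a log2 ratio of 1 or more in size and a small FDR, so the tables hold 807 models in Col and 1001 in ein3eil1 and not all genes. The deposited p-values were recovered within 0.482% (749 models of Col) and 0.463% (944 models of ein3eil1) by the Audic-Claverie probability of 2 read counts, doubled for 2 sides, a test of 2 libraries that knows no spread between plants. From the ranks behind the deposited FDR values, the number of models tested was worked out as 28748 to 28767 in Col and 28608 to 28620 in ein3eil1. The last listed model held a rank of 4117 to 4121 in Col and 4782 to 4785 in ein3eil1, so about 19.6% and 20.9% of the models with an FDR this low are listed.

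Ratios were computed from the deposited RPKM values without a pseudocount. Models with 1 RPKM or more in at least 1 library of the table, or in any of the 4 libraries for shared models, were counted when at least 2-fold higher or lower. With 1 library per group no test across samples and no p-value was made. Each ratio has a 95% interval from the exact Clopper-Pearson interval of the share of reads in the Cd library, and a difference of log2 ratios has a normal interval from the 4 read counts. Reads from PCR-amplified libraries are not independent molecules, so these intervals cover counting error only. A fold against 0 reads was set against a floor of 3 reads, or 0.156 to 0.179 RPM (reads scaled to the library total) in the 4 libraries. The steps were tested on simulated data: the intervals held the true ratio for 95.2% of 807 models simulated for Col and 95.8% of 1001 for ein3eil1, and a simulated number of 28000 tests lay within the range recovered, which was 27997 to 28003 for Col and, with a loose upper end, 27996 to 39852 for ein3eil1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

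Coordinates are those of the deposited tables, whose build is not named. Set against NCBI's TAIR10.1 annotation, 806 of 807 and 1000 of 1001 models matched a gene identifier, and 796 and 990 of these lay within 200 bases of the annotated gene. That annotation was used for gene names and for the number of transcripts of a locus, and none of its coordinates is printed. Reads of genes with near-identical copies, of overlapping genes and of several transcript models of a locus can have been split between models in ways that these tables do not show.

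Before the data were examined, 25 gene lists with 364 entries (6 of them tissue or zone markers) and 15 description patterns were fixed. All 364 entries were in the annotation, 341 under the same symbol and 23 under another or no symbol. A list counts loci, taking the model with the most reads. The genes named were, for each Cd response, the 8 highest and 8 lowest log2 ratios with 10 RPKM or more in the higher library, and from each list up to 4 members with the largest log2 ratio in size among those with 1 RPKM or more. EIN3, EIL1, XTH33 and LSU1 were always named. For the genotype comparison they were the 8 largest differences in each direction and the 6 highest and 6 lowest models listed in 1 table, and for the untreated comparison the 6 highest and 6 lowest, each among models with 10 RPKM or more in at least 1 library of the table, or of both tables for shared models, so that a shared model could pass in a Cd library. Other genes named (SULTR1;1, SULTR1;2, SULTR2;1, SDI2, APR3, NAS2, LOX3, LOX4, WRKY40, WOL, GSTU10, GSTU11, GSTU22 and XTH32) were chosen after their values were seen, as were 7 further lists, and the members named from them, in the closing section. Alternatives planned were another fold threshold, another minimum, a pseudocount of 1, centred ratios, a stricter FDR and the models in both tables, and others were added after the data were seen: a minimum of 10 reads, 1 model per locus, loci with 1 reference transcript, a pseudocount of 0.1, 3 reads in place of 0 and, for the untreated comparison, 1 RPKM in an untreated library. Every value column of the tables was used.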

Results

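Root transcripts of Arabidopsis thaliana seedlings were sequenced in 4 libraries: the wild type Col and the ein3eil1 double mutant, each untreated and after 6 h with 150 µM CdSO4. EIN3 and EIL1 are transcription factors that act at the end of the ethylene signalling pathway. The seedlings were 5 days old, and the labels name the tissue as root tip and primary root. Each group had 1 library, so no difference below has a replicate check. The controls are entered as 0 µM and 0 h, which does not show whether they were kept for the same 6 h. If they were not, time and handling cannot be told apart from Cd. The libraries held 19192279 reads (Col control), 16773595 (Col with Cd), 16993296 (ein3eil1 control) and 16802110 (ein3eil1 with Cd). Intervals of ratios are 95% exact counting intervals, and those of differences of log2 ratios are 95% normal intervals. Both cover counting error only. The deposited tables hold gene models past the authors' thresholds, so a gene that is not listed can have changed less than 2-fold, can have too few reads, or can be missing for another reason. Neither EIN3 (AT3G20770) nor EIL1 (AT2G27050) was listed, so the mutant genotype could not be checked from these values.

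The first comparison asked how Cd changed the root transcriptome of the wild type. Among models with 10 RPKM or more, the 8 highest ratios with Cd were those of the low-sulfur genes BGLU28, LSU1 and LSU3, a carbonic anhydrase, a defensin-like gene, 2 cupins and AT1G65500, of unknown function. BGLU28, a beta-glucosidase, stood at 0.0534 RPKM in the control and 26.7 RPKM with Cd, a 499-fold ratio (interval 138 to 4126) that rests on 2 control reads. LSU1 (chromosome 3, 18375269 to 18375784) went from 1 read to 126 reads, or 0.101 to 14.6 RPKM, a 144-fold ratio with an interval from 25.4 to 5739. At the other end, ATCSLB05, a cellulose synthase-like gene, was 109-fold lower (49.8 to 298) and CER4, a fatty acyl-CoA reductase, was 38.2-fold lower (22.2 to 72.2). The iron uptake genes FRO2 and IRT1 were 13.5-fold and 12.9-fold lower.

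Of the 16 genes in the sulfur limitation list, 14 were higher in Col and none was listed as lower. LSU3 was 32.3-fold higher (12.3 to 121), SDI1 25.4-fold (14.3 to 49.7), the glutathione-degrading GGCT2;1 13.7-fold (9.26 to 21.2) and LSU2 6.87-fold (4.51 to 10.8). The sulfate transporter SULTR1;1 had 17 RPKM without and 88.6 RPKM with Cd, and SULTR1;2 had 13.2 and 73.3 RPKM. ATBCA3, a beta carbonic anhydrase, had 0.628 RPKM in the control and 76.2 RPKM with Cd. The defensin-like gene AT4G11393 had 1.1 and 153 RPKM. The cupin genes AT5G39110 and AT5G39120 were 40.9-fold and 32.8-fold higher, and AT1G65500 was 44.3-fold higher.

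Heat shock genes were higher in 12 of 28 list members, and none was listed as lower. The small heat shock proteins HSP17.4, HSP17.6C and HSP17.6A were 11.5-fold, 11.3-fold and 11.1-fold higher, each from 13 or fewer control reads. BIP3, an endoplasmic reticulum chaperone, went from 1 to 71 reads, an 81.2-fold ratio with an interval from 14.1 to 3253. Glutathione S-transferases, which join glutathione to other molecules, were higher in 9 of 19 members. GSTU12 was 10.7-fold higher (7.25 to 16.2), and GSTU24 went from 55.9 to 222 RPKM. In the glutathione and phytochelatin list 3 of 9 members were higher: GR1 by 2.89-fold, the vacuolar transporter ABCC3 by 2.67-fold and the phytochelatin synthase PCS2 by 2.14-fold. None of these 3 reached 5 RPKM, and the GR1 value is that of the model AT3G24170.3. In the oxidative stress list, CSD1 was 2.6-fold and NDB2 2.04-fold higher among 21 members, and the sign of NDB2 turned when ratios were centred on the median of listed models. That median was log2 1.06 in Col and 1.16 in ein3eil1, as no listed ratio lies between -1 and 1. Higher ratios below it turn sign by arithmetic, here and in later mentions, and the median is no estimate of a scaling error.

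In the iron deficiency list 5 of 24 members were lower and 1 was higher. FRO2, the ferric chelate reductase (chromosome 1, 209395 to 213041), went from 86.2 to 6.38 RPKM. IRT1, the iron transporter, went from 59.7 to 4.63 RPKM. NAS2, a nicotianamine synthase, was the higher member, at 13.7 RPKM without and 35.3 RPKM with Cd. The metallothionein MT2A was 2.43-fold lower (2.18 to 2.71), and no other member of the 14 metal transport and binding genes was listed in Col.

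Nitrate transport genes were higher in 4 of 9 members. The transporter NRT2.1 went from 106 to 331 RPKM, NRT1.8 from 22.5 to 77.3 RPKM, NRT3.1 from 12.3 to 39.1 RPKM and NRT2.4 from 0.921 to 4.03 RPKM. Defence genes were higher in 5 of 21 members, among them CYP71A12 (5.46-fold), CYP81F2 (3.91-fold), FRK1 (2.92-fold) and WRKY30 (2.73-fold). In the jasmonate list, LOX3 and LOX4 were the 2 listed members of 23, both higher, though the sign of LOX3 turned on that centring. For ethylene itself, ACO4, which makes ethylene from its precursor, was 2.54-fold higher (2.34 to 2.76). ACS5, which makes that precursor, went from 26 to 2 reads, an 11.4-fold lower level with an interval from 2.84 to 98.8. None of the 15 ethylene perception and signalling genes and none of the 19 ERF factors was listed in Col.

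Among cell wall genes, XTH33 (chromosome 1, 3479153 to 3480988) was 2.14-fold lower (1.64 to 2.82) and XTH23 was 2.04-fold lower, the 2 listed members of 21 xyloglucan endotransglucosylases. EXPA10 was the 1 listed expansin of 10, 3.05-fold higher. The auxin-induced genes GH3.3 and LBD16 were 3.66-fold and 2.27-fold higher, 2 of 12 members of the auxin response list, and none of 14 auxin synthesis and transport genes was listed. The glucosinolate pathway genes IPMI1 and CYP79F2 were 13.7-fold and 12.8-fold lower. The sulfotransferase gene ATST4B was 16.1-fold lower, and the lipid-transfer protein gene AT5G46890 was 34.6-fold lower.

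Altogether 427 models were at least 2-fold higher and 342 at least 2-fold lower in Col among those with 1 RPKM or more in either library. The largest FDR in the authors' deposited table for Col was 0.000967, from a comparison of the reads of 2 libraries, which compares those libraries and not the conditions. With ratios centred on the median of the listed models, the split was 108 higher and 342 lower, and 273 were higher at 5 RPKM and 284 with a pseudocount of 1.

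**Figure D1:**
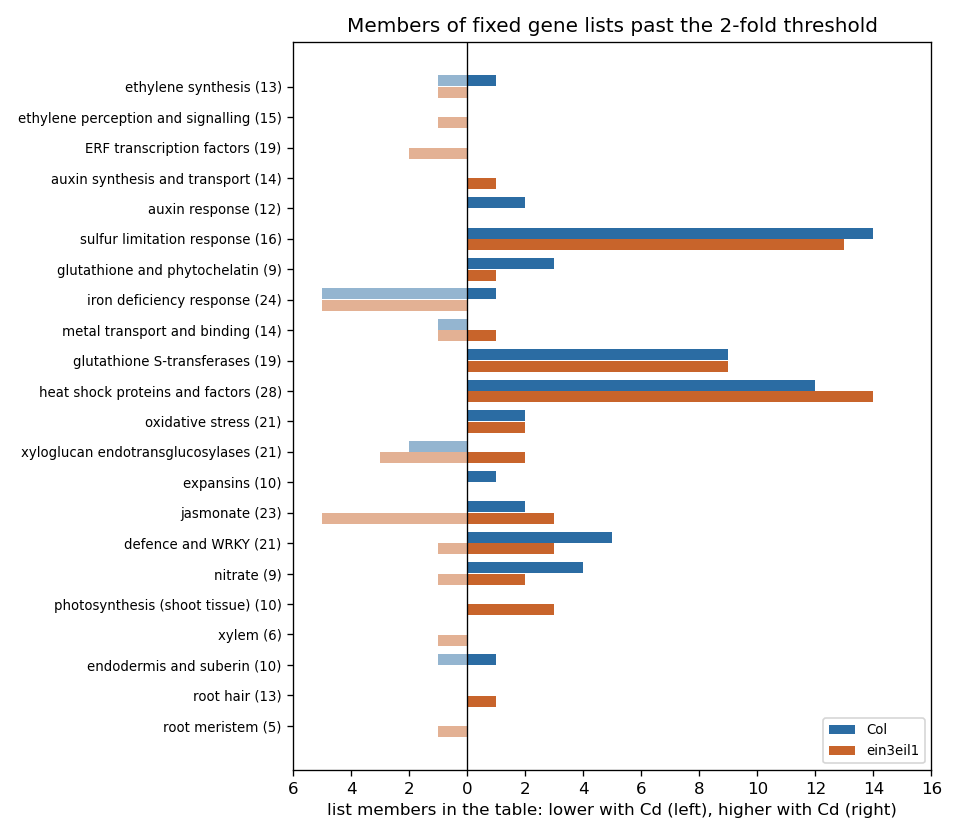
Bars give, for each gene list, the number of members listed as at least 2-fold higher with Cd (right, full colour) or lower with Cd (left, pale) in Col and ein3eil1, with the list size in brackets. The sulfur limitation list has 14 higher members in Col and 13 in ein3eil1, and after centring on the median of listed models 3 glutathione S-transferases of ein3eil1 would lie below 0.

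The second comparison put the same question to the mutant. Among models with 10 RPKM or more, LSU1 and BGLU28 had the highest ratios: BGLU28 went from 0.151 to 54.1 RPKM and LSU1 from 0.114 to 51.6 RPKM, or from 1 to 447 reads. AT4G11393 was 165-fold higher (64.2 to 608). SDI1 was 114-fold higher (48.6 to 353) and LSU3 51.5-fold higher (26.9 to 113). With the same minimum, the lowest ratio was that of ATCSLB05, 156-fold lower (66.5 to 481). The glucosinolate pathway genes CYP79F2, MAM1, IPMI1 and GSTF11 were 14.5-fold, 13.1-fold, 9.98-fold and 8.82-fold lower. CER4 was 11.3-fold lower. The low-oxygen response genes PCO2 and SAD6 were 10.9-fold and 11-fold lower.

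In the sulfur limitation list 13 of 16 members were higher in ein3eil1, and none was listed as lower. LSU2 was 11.4-fold higher (8.4 to 16) and GGCT2;1 22.4-fold (12.3 to 45.5). SULTR1;1 had 3.08 RPKM without and 32.5 RPKM with Cd, while SULTR1;2 was not listed. Heat shock genes were higher in 14 of 28 members: HSP17.6A 6.14-fold, HSP17.4 3.89-fold, and BIP3 26.3-fold with an interval from 8.67 to 130. ROF2, a chaperone-type isomerase, was 5.37-fold higher. Glutathione S-transferases were higher in 9 of 19 members, with GSTU12 8.4-fold, GSTU4 4.75-fold, GSTF6 4.5-fold and GSTU24 2.24-fold, though centring on the median of listed models turned the sign of GSTU10, GSTU11 and GSTU22. The vacuolar transporter ABCC2 was the 1 listed member of 9 glutathione and phytochelatin genes, 2.55-fold higher. This value is that of the model AT2G34660.2, which went from 40 to 101 reads, or 0.44 to 1.12 RPKM. OPR1 and NDB2 were higher in the oxidative stress list, by 2.56-fold and 2.28-fold.

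Iron deficiency genes were lower in 5 of 24 members and higher in none of those listed. FRO2 went from 51.4 to 8.94 RPKM, IRT1 from 53.7 to 10.8 RPKM and CYP82C4 from 5.56 to 1.37 RPKM. S8H, which makes coumarins that help take up iron, went from 121 to 4 reads, 29.9-fold lower (11.4 to 112). MT2A was 2.18-fold higher (1.92 to 2.49), a sign that turned with centring on the median of listed models. HMA3, a heavy metal ATPase gene, was 2.31-fold lower (1.45 to 3.77), from 63 to 27 reads, or 1.62 to 0.702 RPKM. XTH33 was 9.04-fold lower (5.2 to 17), from 128 to 14 reads. XTH23 and XTH31 were 2.18-fold and 2.07-fold lower, and XTH26 was 4.8-fold higher. In all, 3 of 21 xyloglucan endotransglucosylases were lower and 2 were higher, of which XTH32 turned sign with that centring. No expansin of 10 was listed.

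Ethylene genes were few: ACS5 went from 33 to 3 reads, 10.9-fold lower with an interval from 3.41 to 55.4. The receptor ETR2 was 2.61-fold lower, the 1 listed member of 15 perception and signalling genes. ERF109 and HRE1 were 3.15-fold and 2.93-fold lower, 2 of 19 ERF factors. In the jasmonate list 3 of 23 members were higher and 5 lower. VSP2 went from 1 to 34 reads, 34.4-fold higher with an interval from 5.77 to 1398, AOC2 was 3.16-fold and LOX2 3.08-fold higher, and the repressor JAZ10 was 3.79-fold lower. The JAZ10 value is that of the model AT5G13220.3, from 46 to 12 reads (interval 1.98 to 7.86), and the HRE1 value that of AT1G72360.2. Defence genes were higher in 3 of 21 members, led by CYP71A12 (5.29-fold) and CYP81F2 (3.03-fold), while WRKY40 went from 179 to 75.4 RPKM. Among 9 nitrate genes NRT1.8 was 4.51-fold and NRT2.4 2.85-fold higher, and NRT3.1 was 2.65-fold lower. YUC9, an auxin synthesis gene, was 2.15-fold higher, the 1 listed member of 14, with a sign that turned on centring, and none of 12 auxin response genes was listed.

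In ein3eil1, 594 models were higher and 358 lower. With ratios centred on the median of the listed models the split was 133 higher and 358 lower, and 362 were higher at 5 RPKM and 386 with a pseudocount of 1. At loci with 1 transcript in the reference annotation, 280 were higher in ein3eil1 and 277 in Col, and at loci with several transcripts 307 were higher in ein3eil1 and 146 in Col. The largest FDR in the authors' deposited table for ein3eil1 was 0.000987.

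Marker genes of tissues and zones were listed in small numbers. None of 10 photosynthesis genes was listed in Col, and 3 were higher in ein3eil1: RBCS3B 3.17-fold, LHCB2.1 2.37-fold and RBCS1A 2.27-fold. The xylem peptidase XCP2 went from 193 to 85.7 RPKM in ein3eil1, the 1 listed marker of 6. Of 10 endodermis and suberin genes, CASP1 was 2-fold lower and FAR4 4.23-fold higher in Col, and none was listed in ein3eil1. PRP1, expressed in root hairs, was 3.01-fold higher in ein3eil1, the 1 listed of 13 root hair genes. Of 5 root meristem genes, WOL was listed as lower in ein3eil1, at under 1 RPKM in both libraries. No member of the cell cycle (17 genes), DNA damage (10 genes) or root cap (5 genes) lists was listed in either genotype.

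**Figure D2:**
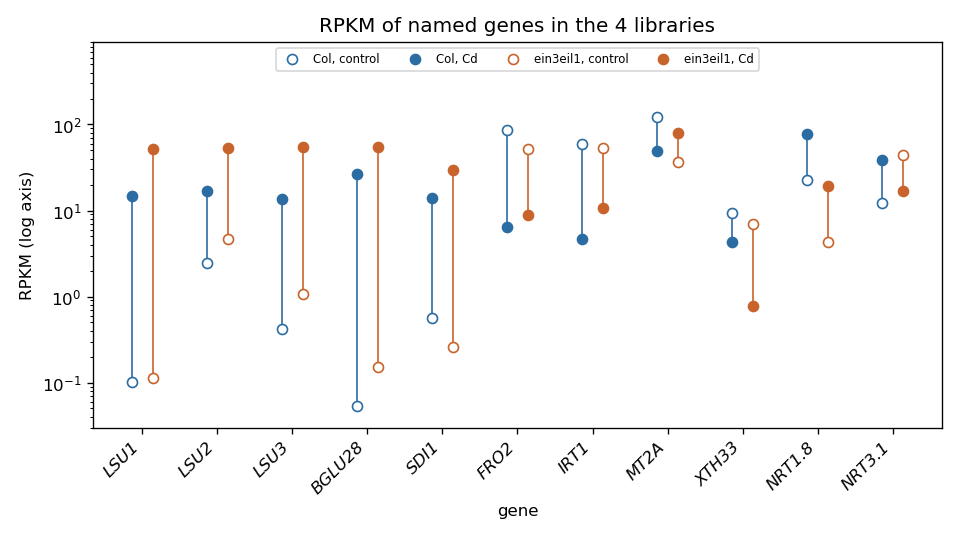
Each pair of circles joined by a line gives the RPKM of 1 gene in the control library (open) and the Cd library (filled) of Col (blue) and ein3eil1 (orange), on a log axis, with 1 library per circle and no error bar. LSU1 lies at 14.6 RPKM with Cd in Col and 51.6 in ein3eil1, XTH33 at 4.35 and 0.780, and the lines of MT2A and NRT3.1, both at loci with several reference transcripts between which reads can be divided, run in opposite directions in the 2 genotypes, with MT2A in ein3eil1 turning sign on centring.

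The third comparison asked whether the response to Cd differed without EIN3 and EIL1. Most genes listed in both tables moved the same way: 154 models were higher in both, 109 lower in both and 27 in opposite directions. Shared models made up 35.9% of those listed for Col and 29.0% of those listed for ein3eil1. A further 517 models were listed for Col only and 711 for ein3eil1 only, so this agreement covers the smaller part of each list. The 27 became 15 at an FDR of 1e-05 or less in both of the authors' deposited tables, 11 at loci with 1 reference transcript and 2 at 4-fold in both. The low-sulfur gene SDI1 had a larger ratio in ein3eil1, by 2.17 on the log2 scale (difference -2.17, interval -3.69 to -0.65). Members of the sulfur limitation list differed both ways: of 13 shared models, 3 had an interval above 0 (SDI2, SULTR2;1 and APR3, with differences of 0.68, 0.49 and 0.47), 2 had one below 0 (SDI1 and SULTR1;1) and 8 had one that held 0. XTH33 was lower in both, and more so in ein3eil1 (difference of log2 ratios, Col minus ein3eil1, 2.08, interval 1.2 to 2.96). For FRO2 and IRT1 the lower level with Cd was more marked in Col (differences -1.23 and -1.38). For LSU1 the difference of -1.65 had an interval from -5.66 to 2.36, so that a difference was not detectable at this depth.

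Among shared models with 10 RPKM or more in at least 1 library, the 8 most positive differences belonged to models that were higher with Cd in Col and lower in ein3eil1. SAD6, a fatty acid desaturase gene, had the largest (4.62, interval 4.04 to 5.21): it went from 2.53 to 5.66 RPKM in Col and from 24.3 to 2.21 RPKM in ein3eil1. The 60S acidic ribosomal protein gene AT5G47700 (3.18), the small nucleolar RNA gene AT4G39363 (3.18), NRT3.1 (3.07), the methyltransferase gene FAMT (2.69) and TIM10, for a mitochondrial import protein (2.68), followed. AT2G20820 (2.69) and AT4G09260 (2.46) have no known function. With the same minimum, the most negative differences were those of the glycine-rich protein gene AT2G05510, the cysteine protease gene AT1G29090 (-6.92), the ribosomal protein genes AT5G08180 (-5.08) and AT5G22440 (-3.25), the aconitase gene ACO1 (-3.72), AT5G46890 (-2.83), mtACP3, for a mitochondrial acyl carrier protein (-2.83), and MT2A (-2.41). AT2G05510 had 0 reads in untreated ein3eil1 and 13 with Cd, at least 4.38-fold higher against a floor of 3 reads, and was 2.01-fold lower in Col. Its place as the first named rests on the 0.001 RPKM entered for 0 reads. With 3 reads in place of 0 its difference was -3.14 (interval -4.97 to -1.31), smaller in size than those of AT1G29090, AT5G08180, ACO1 and AT5G22440. Of the 15 named models with opposite directions, SAD6, AT1G29090, AT4G09260, FAMT and AT4G39363 lie at loci with 1 reference transcript and 10 at loci with several, where the division of reads between models is not known. With centring, the small ratios of TIM10 and AT5G47700 in Col and of MT2A in ein3eil1 turned sign.

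Among models with 10 RPKM or more that were listed for Col and not for ein3eil1, the highest were the 2 cupins, the receptor-like kinase gene CRK10 (6.85-fold, 5.61 to 8.42) and, of unknown function, AT1G65500, AT1G21520 (20.7-fold) and AT5G36925 (6.01-fold). The lowest with this minimum were CASP5, a Casparian strip gene (6.44-fold lower), the raffinose synthase gene DIN10 (5.13-fold), the oleosin-like gene AT5G56100 (4.59-fold), AT3G15450 (4.4-fold) and the amino acid transporters UMAMIT17 (4.38-fold) and UMAMIT20 (3.84-fold). The DIN10 value is that of the model AT5G20250.4. Another model of this gene, AT5G20250.2, was listed as lower in both genotypes, from 88 to 27 reads in ein3eil1. With the same minimum, the highest among models listed for ein3eil1 and not for Col were ECS1 (21.2-fold), DFR, of anthocyanin synthesis (5.43-fold), ROF2, the lignin gene CCR1 (4.12-fold) and the isocitrate lyase gene ICL (3.94-fold), with AT2G41730, of unknown function, 4.27-fold higher. The lowest with this minimum were PCO2 (10.9-fold), AT4G33560 (6.74-fold), AT1G19900 (6.25-fold), PCO1 (5.4-fold), AT3G27220 (4.41-fold) and BPS3 (4.36-fold). A gene past the thresholds in 1 genotype is not shown to differ between them, and that difference was not tested.

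Of the 285 shared models with 1 RPKM or more in any library, 36 had a log2 ratio at least 1 larger in Col, 32 had one at least 1 smaller, and 217 lay within 1. The 36 became 23 at 5 RPKM and 21 with a pseudocount of 1, and at loci with 1 reference transcript 21 were larger and 18 smaller. Across the 280 models with reads in every library, Pearson's r of the log2 ratios was 0.861 and Spearman's rho 0.824, over genes, which are not independent replicates and were listed for having changed. The same direction held for 90.7% of the 290 shared models (exact binomial interval 86.7 to 93.8, with models taken as independent). Independent lists of these sizes among 28608 tested models would share 9.92 models higher in both, 4.62 lower in both, 5.79 higher in Col and lower in ein3eil1 (18 observed), and 7.91 of the reverse kind (9 observed). Tested models with too few reads to be listed count among the 28608, so these expected numbers can be too low.

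**Figure D3:**
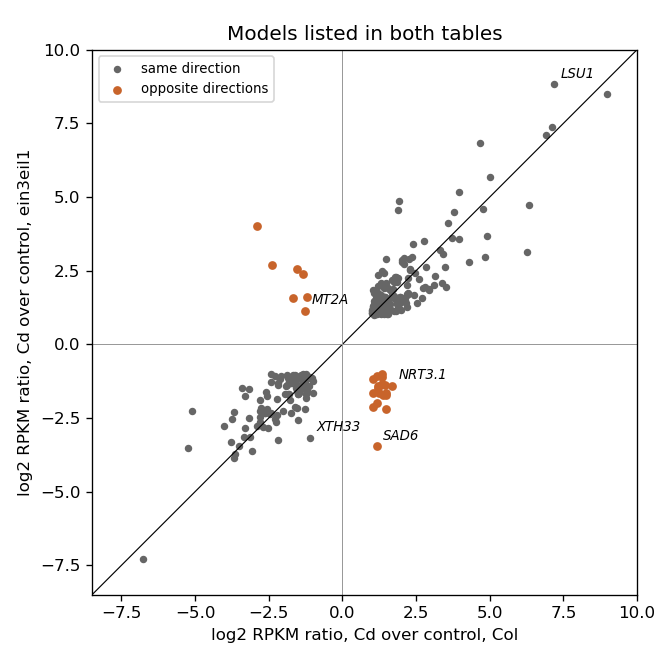
Each of the 280 points is a gene model listed in both tables with reads in every library, at its log2 RPKM ratio of Cd over control in Col (x axis) and in ein3eil1 (y axis), with the line of equal ratios. Most points lie in the 2 quadrants of equal sign, and orange points mark models with opposite directions, such as SAD6, at a locus with 1 reference transcript, and NRT3.1 and MT2A, at loci with several, of which MT2A turns sign in ein3eil1 on centring.

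The fourth comparison set the untreated mutant beside the untreated wild type, over models listed in both tables, which are values from separate tables scaled by each library's own total. Among those with 10 RPKM or more in any of the 4 libraries, small heat shock genes were higher in untreated ein3eil1: HSP17.4 by 12.2-fold (0.936 against 11.4 RPKM), HSP17.6A by 11.9-fold and HSP17.6II by 6.62-fold. The methyltransferase gene FAMT was 14.9-fold higher, ANNAT4, an annexin, 11.3-fold (6.82 against 77.3 RPKM) and SAD6 9.62-fold. With the same minimum, the lowest in ein3eil1 were AT2G05510, at least 121-fold lower, AT1G29090 (85-fold, from 384 reads in Col to 4), AT5G40590 (19.7-fold), AT1G19530 (11.1-fold), ATBCA3 and AT5G08180 (5.81-fold). For ATBCA3, with 1 read in ein3eil1 and 12 in Col, the log2 ratio of -3.41 had an interval from -8.83 to -0.65. NRT1.8 was 5.23-fold and MT2A 3.32-fold lower in untreated ein3eil1. Of the 285 shared models with 1 RPKM or more in any of the 4 libraries, 74 were at least 2-fold higher and 46 at least 2-fold lower in untreated ein3eil1, with a median log2 ratio of 0.33. With Cd, 65 were higher and 45 lower. In the untreated comparison 48 were higher with a pseudocount of 1, and 27 were lower at loci with 1 reference transcript.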

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

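All tests in this part were chosen after the results were seen. In 1 library each, 27 models moved one way with Cd in Col and the other way in ein3eil1, and none of these differences was tested against a spread between plants. The named ones, with the log2 ratio in Col minus that in ein3eil1, were SAD6 (4.62), AT4G39363 (3.18), AT5G47700 (3.18), NRT3.1 (3.07), FAMT (2.69), AT2G20820 (2.69), TIM10 (2.68) and AT4G09260 (2.46) on the positive side. On the negative side they were AT1G29090 (-6.92), AT5G08180 (-5.08), ACO1 (-3.72), AT5G22440 (-3.25), AT2G05510 (-3.14, with 3 reads in place of 0), mtACP3 (-2.83) and MT2A (-2.41).

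A candidate explanation for these opposite directions is that reads were divided between transcript models of a locus differently in each library. Opposite models were 16 of 99 shared models at loci with several transcripts (16.2%, exact interval 9.53 to 24.9) and 11 of 188 at loci with 1 transcript (5.85%, 2.96 to 10.2). Both intervals take models as independent draws. The 11 argue against divided reads as the whole cause, since those loci have no second model in the reference annotation. For the 16 others, which include 10 of the 15 named models (NRT3.1, MT2A, ACO1, TIM10, mtACP3, AT2G05510, AT5G08180, AT5G22440, AT5G47700 and AT2G20820), the explanation cannot be told apart from a genotype effect, because another listed model moving the reverse way was found for 0 of them and models that are not listed have no value here. The named models also differed between the untreated libraries. Those with a positive difference lay higher in untreated ein3eil1 than in untreated Col (log2 ratio 3.27 for SAD6 and 1.86 for NRT3.1). Those with a negative one lay lower (-1.95 for ACO1 and -1.73 for MT2A). With Cd these genes had ratios of -1.36, -1.22, 1.77 and 0.68 in that order. The difference of log2 ratios equals the untreated log2 ratio, ein3eil1 over Col, minus the same ratio with Cd. Choosing models by large differences thus favours untreated ratios of the same sign, so these untreated ratios are no separate evidence. An unusual untreated library was not tested, and 1 library per group cannot tell it from a genotype effect. A response that depends on EIN3 and EIL1 stays open and untested with 1 library per group.

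More models were higher with Cd in ein3eil1 than in Col, 594 against 427. Of the higher models at loci with 1 transcript, 50.3% belonged to ein3eil1 (280 against 277, exact interval 46.0 to 54.5), and at loci with several transcripts 67.8% did (307 against 146, 63.3 to 72.1). These intervals and the next treat models as independent draws, although models listed for both genotypes count on both sides. Divided reads should also lower some models, yet of the lower models at loci with several transcripts 52% belonged to ein3eil1 (144 against 133, 45.9 to 58), and loci with several listed models were 11 in ein3eil1 and 14 in Col. Of all listed higher models, 88 of 632 in ein3eil1 and 20 of 449 in Col had an identifier ending in a number other than 1. Of the listed lower models, 40 of 369 in ein3eil1 and 35 of 358 in Col did. Such models were thus more frequent among the higher models of ein3eil1, which divided reads could give. Even so, divided reads cannot be told apart from a change limited to genes with several transcripts. A model that lost few of its reads would not be listed. Sequencing depth is argued against, as the ein3eil1 libraries held 0.940 times the reads of the Col libraries.

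In ein3eil1, 16 of 24 low-oxygen genes and 10 of 21 wound and touch genes were listed as lower with Cd, in lists chosen after the values were seen and not tested for enrichment. A scaling error of the ein3eil1 libraries could lower listed models as a group, and 36.9% of them were lower. That share cannot exclude a smaller error, because the share without one is not known from models past 2-fold. A high starting level in the untreated ein3eil1 library, from handling or from the genotype, stays open. Of the 5 members in both tables, 3 (SAD6, PROPEP1 and LOX3) were at least 2-fold higher in untreated ein3eil1 than in untreated Col, and AT1G19530 and AT1G33055 were not. SAD6, PROPEP1 and LOX3 were also those higher with Cd in Col, while AT1G19530 and AT1G33055 were lower in both genotypes. These values cannot decide the question, because the untreated ein3eil1 level is part of the ratio by which members were counted as lower. With 1 untreated library per genotype, handling and genotype cannot be told apart.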

How the results depend on the processing

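Of the counts and shares recomputed under other settings, 61 stayed within 1.5 times the reported count or within its interval, and 39 moved. No paired analysis was possible because the groups share only replicate number 1. A 1.5-fold threshold for the Cd responses and lists was not run, since the tables stop at 2-fold, nor were TMM or median-of-ratios factors, since the tables do not hold all genes, and no library could be left out with 1 per group. Counts are given as higher, then lower. At 4-fold, the counts were 117 and 85 in Col and 149 and 80 in ein3eil1, with 20 and 18 in the untreated comparison. With 4-fold changes in both genotypes, 44 models were higher in both, 35 lower in both and 2 opposite, with 97.5% in the same direction. At 5 RPKM, 273 models were higher in Col and 362 in ein3eil1, and 23 differences were larger in Col. A pseudocount of 1 gave 284 higher in Col, 386 in ein3eil1, 21 differences larger in Col and 48 higher in untreated ein3eil1. Only models in both tables gave 166 and 115 in Col and 157 and 126 in ein3eil1. A 1.5-fold difference between ratios gave 55 larger and 59 smaller in Col, and a 4-fold one gave 15 smaller. At 1.5-fold, 116 were higher in untreated ein3eil1. An FDR of 1e-05 or less in both of the authors' tables gave 15 opposite models. Added after the data were seen were a minimum of 10 reads, 1 model per locus, a pseudocount of 0.1, 3 reads in place of 0, 1 RPKM in an untreated library (66 and 43 in the untreated comparison) and loci with 1 reference transcript. The last of these gave 277 and 204 in Col, 280 and 210 in ein3eil1, 21 and 18 differences, 27 lower in untreated ein3eil1, and 11 opposite models, with 94.1% in the same direction. Each of these settings leaves fewer or more models by construction.

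Centring on the median of the listed models (log2 1.06 in Col, 1.16 in ein3eil1) left 108 higher in Col and 133 in ein3eil1, and 23 and 20 higher list members. Because no listed ratio lies between -1 and 1, this median follows the number of higher and lower models and is no estimate of a scaling error. Of the genes recomputed one by one, it turned the sign of YUC9 (-0.0628) and MT2A (-0.0379) in ein3eil1 and of NDB2 (-0.0337), TIM10 (-0.0314) and AT5G47700 (-0.0218) in Col. Among other list members it also turned LOX3 in Col and GSTU10, GSTU11, GSTU22 and XTH32 in ein3eil1. For the genes recomputed one by one and for the lists, 354 values stayed within their interval (lists within 1.5 times), 215 moved and 5 turned sign. A pseudocount of 1 moved 63 of 190 and that centring 146 of 194. Genes with 1 to 5 reads in a library, such as LSU1, BGLU28 and ACS5, have ratios whose size the depth leaves open.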

Other observations

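The lists named here before the description patterns were chosen after the values were seen, apart from the photosynthesis list, which was fixed before. Genes that make aliphatic glucosinolates, sulfur-rich defence compounds, were lower with Cd in both genotypes: 18 of 27 in Col and the same 18 in ein3eil1, with median log2 ratios of -2.59 and -2.51 over the listed members. MAM3, of methionine chain elongation, had log2 ratios of -2.69 and -2.79, and BCAT4 went from 230 to 22.9 RPKM in Col and from 479 to 54.6 RPKM in ein3eil1. Of 10 indolic glucosinolate genes, 3 were lower in Col and 5 in ein3eil1, among them CYP79B3 (151 to 42.1 RPKM in Col). Of 27 genes known to respond to sugar starvation, 15 were lower and 1 higher in Col, against 4 lower and 1 higher in ein3eil1. BGAL4 went from 171 to 35.3 RPKM in Col and from 55.1 to 26.2 in ein3eil1, so that the 2 genotypes lay closer together with Cd than without. DIN2 was the higher member in both.

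Of 24 low-oxygen response genes, 16 were lower with Cd in ein3eil1, against 2 lower and 1 higher in Col. PDC1, pyruvate decarboxylase, went from 58.1 to 15.1 RPKM and PCO1 from 36 to 6.66 RPKM in ein3eil1, and neither was listed in Col. Of 21 early wound and touch genes, 10 were lower in ein3eil1 and none was listed as lower in Col, where 3 were higher: PROPEP1, TCH3 and LOX3, whose sign turned with centring on the median of listed models. These lists overlap with earlier ones, so their counts are not separate evidence. Among the 10, LOX3, JAZ7, JAZ8, JAZ10 and CYP94C1 are also jasmonate members, ERF109 an ERF factor and WRKY40 a defence gene. ETR2 and HRE1 of the low-oxygen list were counted before among ethylene signalling genes and ERF factors. PROPEP1 had 19.7 and 49.9 RPKM in Col and 103 and 50.9 RPKM in ein3eil1 without and with Cd. Of 12 anthocyanin and flavonoid genes, 4 were higher in ein3eil1 and none was listed in Col. The photosynthesis genes, which mark shoot tissue, went the same way, with 3 of 10 higher in ein3eil1 and none listed in Col. DFR went from 2.47 to 13.4 RPKM, and the regulator PAP1 had 0 and 15 reads, at least 5.06-fold higher.

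Of 22 seed maturation genes, 6 were lower with Cd in Col. OLEO1, PER1, PAP85, AT3G17520 and AT1G72100 had 15 to 32 reads in the control and 0 with Cd, at least 4.37-fold to 9.32-fold lower. The storage protein gene SESA4 had 88 and 13 reads in Col and 133 and 29 reads in ein3eil1.

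Description patterns fixed before the data were examined gave these loci. Aquaporins were lower at 7 loci and higher at 1 in Col, and lower at 4 in ein3eil1. Extensin and proline-rich genes were higher at 11 loci and lower at 1 in ein3eil1, against 2 and 3 in Col. Ribosomal protein genes were higher at 4 and lower at 11 in ein3eil1, against 2 and 3 in Col. Cytochrome P450 genes were higher at 10 and lower at 7 in Col and higher at 16 and lower at 12 in ein3eil1, and UDP-glycosyltransferases were higher at 6 and lower at 1, then higher at 12 and lower at 2. Class III peroxidases were higher at 4 and lower at 6 in Col, against 8 and 3 in ein3eil1. Heat shock genes were higher at 13 in Col, and higher at 15 and lower at 1 in ein3eil1. Glutathione S-transferases were higher at 10 and lower at 3, then 11 and 4, and WRKY genes higher at 5 and lower at 0, then 4 and 3. Auxin-related genes were higher at 3 and lower at 4, then 4 and 2, and chlorophyll-binding and photosystem genes higher at 2 and lower at 3, then higher at 3. Xyloglucan genes were lower at 2 in Col and 3 each way in ein3eil1. Expansins were 1 each way in Col and 1 lower in ein3eil1, histones 1 higher and then 2 lower, and ethylene-related genes 1 higher and then 1 lower.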
